A study of Homo sapiens with 6 samples.

How the data were processed

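Polyadenylated RNA was sequenced from 6 HEK293T samples, 3 titled GFP and 3 titled GFP-exon 6 XIST (here sXIST), as 150-nucleotide paired-end reads. Per the labels' protocols, lentivirus carrying eGFP alone or eGFP with a short XIST isoform was applied for 24 h, the cells were grown for another 24 h and then selected with 5 µg/mL puromycin for 3 days. Libraries were made from 100 ng of total RNA with an integrity number above 8. The authors deposited one table of expected counts per gene, given as whole numbers and not scaled to depth. STAR 2.7.9a, RSEM 1.2.28 and the build GRCh38 are named in the submitters' processing notes, without their roles or order. The gene annotation release and any strand setting of the counting are not given in the sources used here. RSEM divides reads that map to several genes among them, so estimates for pseudogenes, paralogs, readthrough genes and overlapping antisense genes are uncertain, and 22 symbols stood under 2 identifiers with equal values, with 26 tested and 0 called entries.

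The whole-number expected counts were used as deposited. Each of the 63086 entries named a gene. Positions came from GENCODE 29 on GRCh38 for 58072 entries by Ensembl identifier and from RefSeq by symbol for 146, and 4868 entries had no position and stayed out of the chromosome tests. Sample groups and replicate numbers came from the sample titles. Library totals ranged from 18368662 to 25239853 counts.

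Counts were normalized with TMM, filtered with filterByExpr (minimum count 10), and tested for sXIST against GFP with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with group as the only term. Fold changes are sXIST over GFP on a log2 scale, each with a standard error taken as its size divided by the square root of the F statistic. Adjusted p-values are Benjamini-Hochberg values over the 16560 tested genes, and genes under 0.05 were called. CPM values are TMM-normalized and given as mean ± SD over 3 libraries. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. The common biological coefficient of variation was 9.66%. Within each group, no pair of libraries agreed within counting noise.

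X-linked genes other than XIST and TSIX, and 34 gene lists, were tested against all other tested genes with camera in limma 3.58.1, using a preset correlation of 0.01 and again with an estimated correlation. List p-values were adjusted over the 34 lists. Called genes on the X chromosome and on autosomes were compared by two-sided Fisher's exact tests. Intervals of medians are 95% bootstrap intervals from 1000 draws over genes, so they do not measure the spread between libraries. For single values per library, the smallest two-sided p of an exact permutation test with 3 against 3 is 0.1.

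The lists, the tests, most alternatives and the rule for named genes were set before the data were examined. The rule took XIST, the 15 largest rises and 15 largest falls among called genes with at least 1 CPM in one group, a gene symbol and no overlap between the groups' libraries, the 5 X-linked genes with the smallest adjusted p, and up to 4 members of each list. Chance alone would separate the groups' libraries for 10% of genes. Not every gene the rule took is named, and 1 of them is not reported here. Other genes named in the text were chosen after their values were seen.

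The alternatives were DESeq2 size factors, upper-quartile normalization, removal of XIST before library sizes, no count filter, a filter of 1 CPM in 3 libraries, the Wald test of DESeq2 1.42.0, limma-voom, the replicate number as a block, leaving out each library, a test against a fold of 1.2, an adjusted p under 0.01, an estimated correlation and an X set without escape genes. A correction of fold changes for GC content, transcript length and expression level was added after seeing the data. The tests were first run on simulated counts for the 16560 genes of the sXIST and GFP comparison, with 200 genes changed. The edgeR test recovered 58% of 100 genes changed 1.5-fold and 83% of 100 genes changed 2-fold, and 6.62% of its 151 calls were false. The simulation drew each gene independently, with dispersions taken from the real counts. Deviations shared by many genes of a library were not simulated, so these rates may not hold for the real counts.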

Results

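HEK293T cells are a human embryonic kidney line that carries the SV40 large T antigen, a viral protein that binds p53. Transcriptomes were compared between cells transduced with a lentivirus for green fluorescent protein (GFP, n = 3) and cells transduced with a virus for GFP and a short isoform of XIST, named exon 6 XIST in the labels (sXIST, n = 3). XIST is the long noncoding RNA that coats and silences 1 X chromosome in female cells. The GFP libraries held 25239853, 18368662 and 19154043 expected counts, and the sXIST libraries held 18689936, 24067864 and 21743567. The comparison asks how the transcriptome differs when the short isoform is overexpressed.

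XIST rose 2.77-fold in sXIST cells, from 4479 ± 1902 CPM in GFP cells to 12403 ± 354 CPM (SD, n = 3 each; log2 fold change 1.47, SE 0.24, edgeR adjusted p = 0.00572). The GFP cells already held 2658, 4328 and 6453 CPM, and the sXIST libraries held 12623, 12592 and 11994 CPM. TSIX, annotated on the opposite strand, rose from 5.18 ± 1.05 to 68.4 ± 11.9 CPM (log2 fold change 3.74, SE 0.17, edgeR adjusted p = 2.35e-06). On GRCh38, XIST (ENSG00000229807.13) lies on the minus strand of chromosome X from 73820651 to 73852723. Its exon 6, from 73820656 to 73827984, falls inside the single exon of TSIX (ENSG00000270641.2, plus strand, 73792205 to 73829231). Because the counting is not stated to use strand, reads of TSIX and of XIST exon 6 cannot be told apart here, and a gene count does not separate construct from endogenous XIST. Nearby JPX, a noncoding activator of XIST, had a log2 fold change of -0.07 (SE 0.07, edgeR adjusted p = 0.596).

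**Figure D1:**
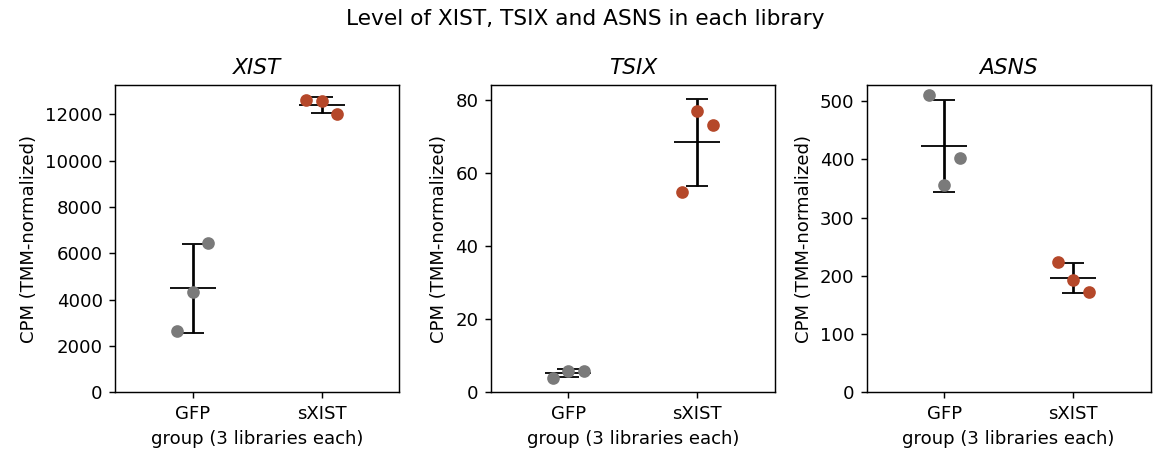
Points are TMM-normalized CPM of XIST, TSIX and ASNS in each of the 6 libraries, by group, with the mean (line) and SD (bars) over 3 libraries. The sXIST libraries lie between 11994 and 12623 CPM for XIST, above the highest GFP library at 6453 CPM, and below the GFP libraries for ASNS.

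In sXIST cells 1008 genes rose and 642 fell among 16560 tested (edgeR, adjusted p under 0.05), and most changes were small. A fold of 2 or more was reached by 169 of the rising and 32 of the falling genes. Among the largest rises were FOXJ1, the master transcription factor of motile cilia, from 0.183 ± 0.090 to 1.35 ± 0.16 CPM (log2 fold change 2.87, SE 0.41, edgeR adjusted p = 0.00282), and DNAAF11, an assembly factor of ciliary dynein arms (2.10, SE 0.37). SCG3, a granin of neuroendocrine secretory granules, rose by a log2 fold change of 2.45 (SE 0.47), and UNC79, a subunit of the NALCN sodium leak channel complex, by 2.38 (SE 0.28). The transcription factors SOX30 (2.17, SE 0.29) and PAX5 (1.95, SE 0.38), the XK-family gene XKR7 (3.62, SE 0.60) and the tetratricopeptide gene TTC34 (2.07, SE 0.25) also rose. These genes stayed low in sXIST cells, between 1.27 CPM for XKR7 and 4.05 CPM for TTC34. The histone gene H4C14 rose from 2.35 ± 0.42 to 15.6 ± 3.8 CPM and H4C8 from 0.246 ± 0.089 to 1.6 ± 0.6 CPM. The rises of COMMD3-BMI1, a readthrough gene, of the pseudogenes PLEKHA8P1 and INTS4P1, of the antisense gene KRTAP5-AS1 and of near-identical H4 histone genes rest on divided or overlapping reads and are uncertain. COMMD3-BMI1 was not called by the DESeq2 Wald test (adjusted p = 0.154). Several of these folds rest on few GFP reads. The GFP libraries held 0, 8 and 19 counts of COMMD3-BMI1, 12, 0 and 0 of PLEKHA8P1 and 2, 0 and 4 of XKR7, so that these folds moved widely when a GFP library was left out and that of PLEKHA8P1 has no upper bound without GFP replicate 1.

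The largest fall was that of HSPA6, a strictly stress-inducible HSP70 on chromosome 1 (161524540 to 161526910, plus strand), from 20.1 ± 11.3 to 0.209 ± 0.118 CPM (log2 fold change -6.51, SE 0.59, edgeR adjusted p = 0.000269). The GFP libraries held 8.4, 31 and 21 CPM of HSPA6. Its paralogs HSPA1A (-0.09, SE 0.39) and HSPA1B (-0.53, SE 0.24) did not pass the test. Among the other large falls were those of INHBE (-1.92, SE 0.42), TRIB3 (-1.48, SE 0.38) and NUPR1 (-1.37, SE 0.23), genes of amino acid and stress responses. KLHDC7B (-3.33, SE 0.72), GDAP1L1 (-2.34, SE 0.59), AKNA (-1.95, SE 0.49), FERMT3, the kindlin of blood cells (-1.71, SE 0.44), the fucosyltransferase FUT1 (-1.61, SE 0.31), the lactate dehydrogenase LDHD (-1.36, SE 0.19), the protocadherin PCDHGB7 (-1.33, SE 0.36) and NDUFA4L2 (-1.31, SE 0.29) also fell. The noncoding RNA LINC01512 (-3.82, SE 0.77) and the pseudogenes KRT18P17 (-2.25, SE 0.38) and SBDSP1 (-2.04, SE 0.41) completed the 15, the pseudogenes being uncertain for shared reads. AKNA and TRIB3 were called neither by DESeq2 (adjusted p = 0.0539 and 0.0726) nor by limma-voom, and KLHDC7B, GDAP1L1, INHBE, FERMT3 and PCDHGB7 were not called by limma-voom. Several of these folds rest largely on GFP replicate 1. TRIB3 stood at 171.9, 46.6 and 62.0 CPM in the GFP libraries, and AKNA at 130.4, 24.0 and 37.3 CPM. LINC01512 had 66, 9 and 15 counts there and dropped below the count filter without GFP replicate 1. Without GFP replicate 1 the log2 fold change was -0.70 for TRIB3, -0.88 for AKNA, -1.23 for INHBE, -2.08 for KLHDC7B and -1.51 for GDAP1L1, the last no longer called (edgeR adjusted p = 0.0943). FERMT3 was at -1.13 without GFP replicate 2 and was not called (edgeR adjusted p = 0.0783).

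The number of calls depended on single libraries. It was 1007 without GFP replicate 3, 740 without sXIST replicate 1, 379 without sXIST replicate 2 and 490 without sXIST replicate 3, and DESeq2 called 1028 rising and 1000 falling genes.

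X-linked genes were slightly lower in sXIST cells as a set. The median log2 fold change of 547 X-linked genes, XIST and TSIX left out, was -0.08 against 0.01 for 15364 autosomal genes, and 64.7% of X-linked genes lay below 0 against 49.1% of autosomal genes (camera p = 0.000306, and p = 0.00320 with an estimated correlation). Relative to autosomes, the median of X-linked genes stood at 0.041, 0.036 and 0.037 on the log2 scale in the GFP libraries and at -0.050, -0.055 and -0.041 in the sXIST libraries, so that all 3 sXIST libraries lay below all 3 GFP libraries. Autosomal medians ranged from -0.03 for chromosome 8 to 0.05 for chromosome 13. Adjusted over 23 chromosomes, the camera p of the X chromosome was 0.00704 and that of each autosome was 0.992, while with an estimated correlation the adjusted p of X was 0.0735.

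**Figure D2:**
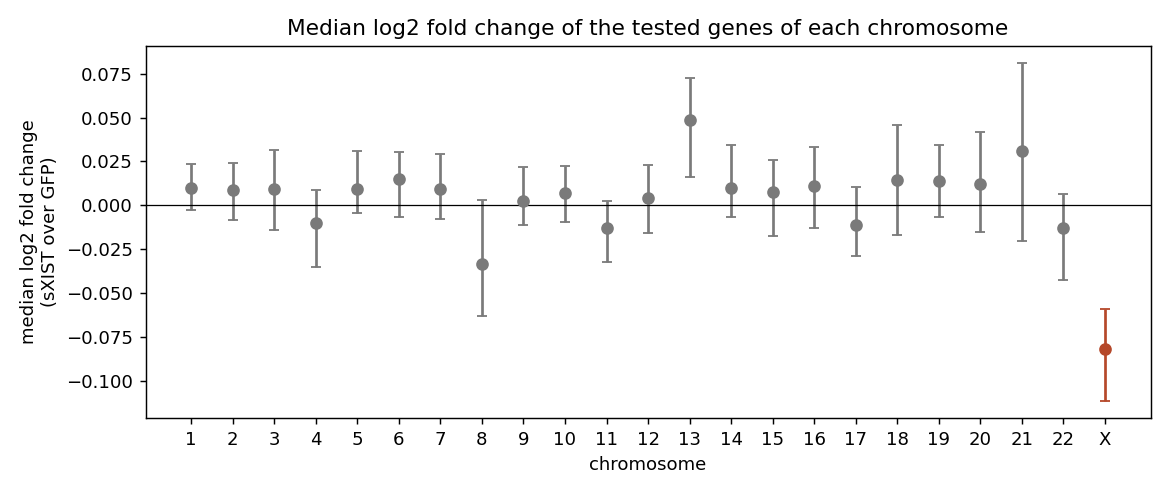
Points are the median log2 fold change (sXIST over GFP) of the tested genes of each chromosome, with 95% bootstrap intervals over genes as bars. The X chromosome, without XIST and TSIX, lies at -0.08 and the autosomes between -0.03 and 0.05.

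Single X-linked genes moved both ways. TSC22D3, the glucocorticoid-induced leucine zipper, fell from 414 ± 82 to 213 ± 16 CPM (log2 fold change -0.96, SE 0.12, edgeR adjusted p = 0.00189). DNASE1L1 fell as well (-0.58, SE 0.10). DRP2, a dystrophin-related gene, rose from 3.27 ± 0.57 to 7.55 ± 0.19 CPM (1.21, SE 0.17), and the splicing factor gene ZRSR2, which escapes X inactivation, rose by 0.61 (SE 0.09). The histone demethylase gene KDM6A, another escape gene, rose by 0.50 (SE 0.09), while the escape gene EIF2S3 fell (-0.31, SE 0.07). Falling calls made up 7.68% of X-linked genes (42 of 547) and 3.89% of autosomal genes (598 of 15364), an odds ratio of 2.05 (95% interval 1.45 to 2.85, two-sided Fisher's exact p = 5.57e-05). Rising calls made up 2.01% (11 of 547) and 6.14% (943 of 15364), an odds ratio of 0.314 (0.155 to 0.569, Fisher's exact p = 8.80e-06). Fisher's exact test treats genes as independent. Genes can vary together between libraries, so these p-values and intervals may overstate the evidence. By Fisher's exact test, the excess of falls was no longer past the threshold without GFP replicate 3 (odds ratio 1.53, p = 0.0601), without sXIST replicate 2 (1.19, p = 0.584), without sXIST replicate 3 (1.51, p = 0.303) or at an adjusted p under 0.01 (1.5, p = 0.395). The deficit of rises stayed past it with each library left out (odds ratios 0.209 to 0.439) and at an adjusted p under 0.01 (0.305, Fisher's exact p = 0.0282).

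Targets of ATF4, the transcription factor of the integrated stress response, were the list with the strongest fall. Of 36 measured members 29 fell and 1 rose (32 and 1 adjusted over the list alone), with a median log2 fold change of -0.59 (camera adjusted p = 3.63e-26, and adjusted p = 0.387 with an estimated correlation). ASNS, the asparagine synthetase, fell from 423 ± 80 to 196 ± 26 CPM (-1.11, SE 0.13, edgeR adjusted p = 0.00127). The cystine transporter gene SLC7A11 (-1.15, SE 0.17), the serine synthesis gene PSAT1 (-0.75, SE 0.13) and the glycine transporter gene SLC6A9 (-0.73, SE 0.10) fell too. ATF4 mRNA, whose protein output is set largely by translation, was 864 ± 40 CPM in GFP and 811 ± 51 CPM in sXIST cells (-0.09, SE 0.08, edgeR adjusted p = 0.509). Library medians of the list ranged from 0.08 to 0.53 in GFP cells and from -0.41 to -0.12 in sXIST cells, each gene being centred on its mean over 6 libraries. The count of falling members was 8 without sXIST replicate 2 and 11 without sXIST replicate 3, and the list stayed called.

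Other lists fell as well, among them those of cytosolic ribosomal proteins, the unfolded protein response and extracellular matrix. Of 77 cytosolic ribosomal protein genes 19 fell and 0 rose (66 and 1 adjusted over the list alone), with a median of -0.27 (camera adjusted p = 1.31e-21, adjusted p = 0.430 with an estimated correlation), among them RPS3 (-0.48, SE 0.10) and RPL21 (-0.39, SE 0.08). The number of called members was 7, 1 and 0 without sXIST replicates 1, 2 and 3. In the unfolded protein response list 4 of 27 genes fell (17 over the list alone, median -0.27, camera adjusted p = 1.56e-07, adjusted p = 0.424 with an estimated correlation), HERPUD1 (-0.62, SE 0.10) and the chaperone gene HSPA5 (-0.42, SE 0.11) among them. Of 30 genes of extracellular matrix and TGF-beta response 10 fell (15 over the list alone, 1 rising; median -0.31, camera adjusted p = 1.56e-07, adjusted p = 0.387 with an estimated correlation), including the collagen genes COL6A1 (-0.54, SE 0.09), COL6A2 (-0.54, SE 0.08) and COL5A1 (-0.59, SE 0.10). Smaller falls were called for antigen presentation by MHC class I (3 of 20 genes, median -0.21, TAP2 at -0.38, SE 0.07), glycolysis (2 of 19, median -0.15, PFKL at -0.36, SE 0.06), fatty acid synthesis under SREBP1 (2 of 16, median -0.13, SREBF1 at -0.46, SE 0.08), X-linked immune genes (4 of 23, median -0.14) and nuclear-encoded oxidative phosphorylation (4 of 73, median -0.09, UQCRH at -0.31, SE 0.06). With an estimated correlation the adjusted p of these 5 lists lay between 0.387 and 0.777. X-linked immune genes were tested against all other genes, and X-linked genes as a whole also had a lower median (-0.08). Whether the immune genes differ from other X-linked genes was not tested. Library medians of the oxidative phosphorylation list overlapped between the groups (-0.04 to 0.14 in GFP and -0.05 to -0.02 in sXIST cells), and 2 members fell over the list alone. The call of oxidative phosphorylation was lost without GFP replicate 2 (median -0.04, camera adjusted p = 0.276), and that of SREBP1 targets without GFP replicate 3 (adjusted p = 0.0661) or sXIST replicate 2 (adjusted p = 0.0532). The counts of falling members also moved when 1 library was left out. They ranged from 1 to 10 for the unfolded protein response, from 3 to 11 for extracellular matrix, from 0 to 7 for oxidative phosphorylation, from 1 to 5 for X-linked immune genes, from 1 to 4 for MHC class I, and from 1 to 3 for both glycolysis and SREBP1 targets. The lowest count was reached with a sXIST library left out in each of these lists, and for X-linked immune genes, MHC class I, glycolysis and SREBP1 targets it was reached without GFP replicate 3 as well (for SREBP1 targets also without GFP replicate 2).

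Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, had the largest median among the lists that rose. Of 22 measured members 8 rose and 0 fell (10 and 0 over the list alone), with a median log2 fold change of 1.08 (camera adjusted p = 2.09e-10, adjusted p = 0.387 with an estimated correlation). H1-2 rose from 3.75 ± 0.40 to 9.30 ± 0.83 CPM (1.31, SE 0.15) and H3C6 from 1.58 ± 0.48 to 5.38 ± 0.50 CPM (1.79, SE 0.24). Library medians of the histone list ranged from -0.54 to -0.48 in GFP cells and from 0.08 to 1.04 in sXIST cells. The median log2 fold change was 0.58 without sXIST replicate 3, with the list still called. A list of other abundant RNAs without a poly(A) tail, chosen after seeing the data, had library medians of -0.84, 0.70 and 0.90 in the sXIST and -0.19, -0.12 and -0.33 in the GFP libraries. None of its members was called.

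Targets of p53 rose in 9 of 26 cases and fell in 1 (10 and 2 over the list alone), with a median of 0.22 (camera adjusted p = 6.43e-05, adjusted p = 0.387 with an estimated correlation). DDB2, a DNA damage recognition gene, rose from 19.2 ± 2.6 to 40.1 ± 5.5 CPM (1.06, SE 0.12), and the nuclease gene AEN from 64.0 ± 8.0 to 128 ± 20 CPM (1.00, SE 0.12), while CDKN1A (0.26, SE 0.11) and MDM2 (0.17, SE 0.07) did not pass the test. Genes of G2 and mitosis rose in 7 of 35 cases (15 over the list alone, 0 falling), with a median of 0.19 (camera adjusted p = 7.83e-06, adjusted p = 0.430 with an estimated correlation), HMMR by 0.59 (SE 0.07) and BUB1 by 0.39 (SE 0.09). The count of rising members was 3 without GFP replicate 1, GFP replicate 3 or sXIST replicate 1, 2 without sXIST replicate 2 and 1 without sXIST replicate 3, and the list stayed called. Among 37 serum response and immediate early genes 8 rose and 2 fell (10 and 3 over the list alone; median 0.26, camera adjusted p = 0.0174, adjusted p = 0.569 with an estimated correlation). JUN rose by 0.42 (SE 0.08) and BTG2 by 0.58 (SE 0.10), whereas MYC fell from 755 ± 145 to 460 ± 14 CPM (-0.72, SE 0.12) and ANKRD1 fell by 1.29 (SE 0.17). That call was lost without GFP replicate 3 (adjusted p = 0.126) or sXIST replicate 3 (adjusted p = 0.0697), and its rising members numbered 1 to 8 over the libraries left out.

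**Figure D3:**
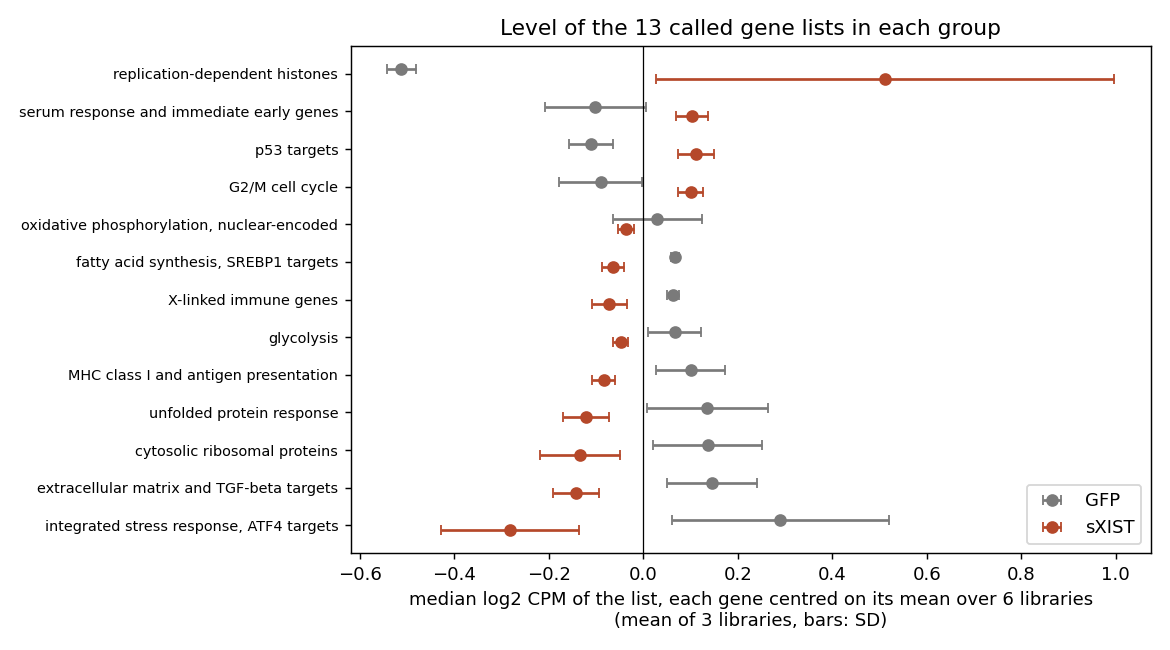
For each of the 13 called lists, points are the mean over 3 libraries of the list's median log2 CPM, each gene centred on its mean over 6 libraries, and bars are the SD. Targets of ATF4 lie highest in GFP cells at 0.29 and lowest in sXIST cells at -0.28, and the sXIST libraries differ most from each other for histone genes (SD 0.48).

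In all, 13 of 34 lists were called with the preset correlation, 4 higher and 9 lower, and 0 were called with an estimated correlation, where the smallest adjusted p was 0.387 and 2 lists had an unadjusted camera p under 0.05. Lists of innate immunity were not called. Of 36 interferon-stimulated genes 2 rose and 1 fell (camera adjusted p = 0.950), of 24 nucleic acid sensing genes 1 rose (adjusted p = 0.806), and of 20 NF-kB and inflammatory genes 2 rose (adjusted p = 0.417), among them LIF (1.63, SE 0.25). Of 33 XIST-binding and silencing factors 4 rose (adjusted p = 0.213), of 34 Polycomb genes 5 rose (adjusted p = 0.576), PHC3 by 0.59 (SE 0.11), and of 37 HOX genes 2 rose (adjusted p = 0.138). Neighbours of the X-inactivation centre had 1 call up, TSIX, and 3 down among 18 genes, with a median of -0.07 but an upward mean and test (adjusted p = 0.806). The mean of 0.15 rests on TSIX (3.74), whose reads cannot be told apart from those of XIST exon 6. The list was not tested without TSIX. Among 28 escape genes 2 rose and 2 fell (adjusted p = 0.380). The broad list labelled noncoding RNAs of nuclear bodies had a median of -0.07 and an upward test (adjusted p = 0.380). Of its 23 genes 3 rose, SNHG15, SNHG12 and PVT1 (from 9.54 ± 1.25 to 24.4 ± 1.7 CPM), and 1 fell, OIP5-AS1. NEAT1 (-0.37, SE 0.23) and MALAT1 (-0.15, SE 0.32) were not called. In the NRF2 and xenobiotic list 2 of 23 genes rose and 4 fell (adjusted p = 0.0688). Few members were called for heat shock (0 up, 1 down of 22, adjusted p = 0.477), SREBP2 and cholesterol synthesis (1 up of 25, adjusted p = 0.757), hypoxia (2 up, 2 down of 24, adjusted p = 0.582), MYC targets and ribosome biogenesis (2 up, 1 down of 32, adjusted p = 0.576), G1/S (3 up, 1 down of 35, adjusted p = 0.970), apoptosis regulators (1 up, 2 down of 26, adjusted p = 0.810) and the mitochondrially encoded genes (0 of 13, adjusted p = 0.327). The heat shock list does not hold HSPA6, and its falling call was DNAJB1 (-0.53, SE 0.12, edgeR adjusted p = 0.0204). The sign of the G1/S median, 0.003, turned with DESeq2 size factors, and the hypoxia list had a median of -0.005, a mean of 0.003 and a downward test. Markers of other cell types were not called either. Neuronal genes known from HEK293 cells had 3 rises, in SNAP25 (1.41, SE 0.25), VGF (1.38, SE 0.33) and CHGB (1.73, SE 0.42), and 1 fall, in NEFL (-0.30, SE 0.08), among 16 (adjusted p = 0.582). Over the list alone 4 rose and 3 fell. Epithelial (0 of 8, median 0.01, mean -0.11, downward test, adjusted p = 0.582), fibroblast (1 down of 14, adjusted p = 0.327) and leukocyte markers (0 of 5, adjusted p = 0.582) showed little. Some lists without a call gained one when a library was left out. Heat shock fell without GFP replicate 1 (camera adjusted p = 0.00349), and the mitochondrially encoded genes without GFP replicate 1 (adjusted p = 0.00185) or sXIST replicate 2 (adjusted p = 0.0110). Both replicate 1 libraries had a lower share of mitochondrial counts (4.55% and 4.62%) than the others (6.39% to 7.45%), and why these calls appeared was not tested. Without GFP replicate 2 the HOX genes rose (adjusted p = 0.0280) and the NRF2 list fell (adjusted p = 0.0157). Over all lists without a call and all libraries left out, at most 5 members were called in either direction.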

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

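The correction for GC content, length and expression level was chosen after seeing the data. The XIST log2 fold change stayed between 1.2 and 1.82 and called in each alternative run for it, and the X minus autosome median stayed between -0.096 and -0.085 and past the threshold, by a p unadjusted over chromosomes, in each alternative run, the corrected value being -0.085 (tested by a Wilcoxon rank-sum test over genes, the others by camera). Adjusted over 23 chromosomes, the camera p with an estimated correlation was 0.0735. The calls numbered 2633 without a count filter, 1195 of them falling, and DESeq2 called 1000 falling genes. Tested against a fold of 1.2, 302 genes passed (239 up, 63 down), and at an adjusted p under 0.01, 392 passed (293 up, 99 down), with an odds ratio for falls on X of 1.5. These stricter tests lower the counts by construction, whereas the causes of the differences without a filter and with DESeq2 were not tested. With an estimated correlation 0 lists were called. Leaving out single libraries gave 379 to 1721 calls, 280 to 1005 rising and 99 to 859 falling, and odds ratios for falls on X of 1.19 to 2.25. Fewer samples lower the power, but why single libraries weigh so differently was not tested.

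With the replicate number as a block 3360 genes were called, 1806 up and 1554 down, including all 1650. The lists called were then 15, the 13 and those of NRF2 (camera adjusted p = 0.0353) and the mitochondrially encoded genes (adjusted p = 0.0455). Deviations from the group mean correlated at 0.276, 0.150 and 0.037 between same-numbered samples, and sXIST replicate 3 correlated best with GFP replicate 2 (0.088). Deviations within a group sum to 0, so these correlations depend on each other and cannot decide whether the numbers pair all samples. The main test was kept without a block, as set before the data were examined. The replicate 1 libraries did stand apart together, on the second principal component (21.4 and 22.9 against 0.52 or lower) and in mitochondrial share (4.55% and 4.62% against 6.39% or more), so a shared handling of these 2 stays open. Over the named genes and the settings that kept all libraries, 1201 comparisons gave the same call, 57 gained it, 18 lost it and 0 reversed. DESeq2 gave no adjusted p for 18 named genes, the filter at 1 CPM removed 9, and LINC01512 also fell out with XIST removed or without GFP replicate 1. When a library was left out, 703 gave the same call, 14 gained it and 260 lost it. Genes near 1 CPM, such as XKR7, rest on few counts (6 in GFP and 82 in sXIST cells), which limits their fold changes.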

Other observations

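Only the splits by calls, lists and odds ratio were chosen before the patterns were seen. The REST and cilium tests and the corrections for GC content, length and level were chosen after the patterns were seen, with bounds set before their own values for the X-linked genes, ATF4 targets, REST and cilia, and the other tests here were chosen after the results they measure were seen. Other genes of motile cilia were higher in sXIST cells alongside FOXJ1 and DNAAF11. In a list of 64 that left out the genes already noticed, 16 rose and 0 fell, with a median log2 fold change of 0.42 (95% interval 0.28 to 0.54, camera p = 8.98e-09, and p = 0.0133 with an estimated correlation, or 0.0667 adjusted over 10 such sets). A wider motile cilium programme stays a hypothesis. Its test passed with the preset correlation, but not with the estimated correlation after adjustment. No correction for GC content, length or level was run for this list. The rise of SNAP25, VGF, CHGB and SCG3 may point to lower repression by REST, the repressor of neuronal genes in other cells. These genes were low in sXIST cells, at 2.69, 1.65, 0.77 and 1.73 CPM. CHGB had 14 counts in GFP and 50 in sXIST cells, and DESeq2 gave no adjusted p for VGF, CHGB or SCG3. NEFL, a more abundant neuronal gene (178 CPM in GFP cells), fell. Other REST targets gave 4 rises among 37 (median 0.10, interval 0.0006 to 0.25, camera p = 0.0377, 0.0753 adjusted over 10 sets, p = 0.482 with an estimated correlation), so this hypothesis failed the correction, and REST mRNA itself was at 0.17 (SE 0.08, edgeR adjusted p = 0.190).

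Zinc finger genes with ZNF symbols, a family of mostly KRAB-type repressors, rose in 96 of 418 cases and fell in 1, with a median of 0.25, and 84.4% of them lay above 0 (camera p = 4.48e-16, and p = 0.00399 with an estimated correlation, 0.0399 adjusted over 10 sets). Corrected for GC content, length and level, the median was 0.20 (interval 0.17 to 0.22). Transcribed unprocessed pseudogenes had a median of 0.44 (7 of 73 rising, 1 falling) and unprocessed pseudogenes one of 0.33 (7 of 63 rising), all uncertain for shared reads. EEF1A1, the translation elongation factor and one of the most abundant mRNAs, fell from 9634 ± 1521 to 6524 ± 522 CPM (log2 fold change -0.56, SE 0.13, edgeR adjusted p = 0.0213).

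The lower level of X-linked genes was not removed by a correction for GC content, transcript length and expression level (median residual -0.10, interval -0.12 to -0.08). Relative to autosomes, the median was -0.087 before and -0.085 after the correction. A copy number change of one segment of the chromosome would leave windows without a fall. Of 7 windows of 20 Mb with at least 20 genes, 7 had a median below 0, from -0.026 to -0.121, but only 5 had their whole 95% interval below 0. The window from 20 to 40 Mb was at -0.031 (interval -0.147 to 0.041) and that from 40 to 60 Mb at -0.026 (-0.084 to 0.006), both inside the range of autosomal medians, so a change of part of the chromosome stays open. Loss of an X copy in part of the sXIST cells cannot be told apart from a chromosome-wide fall by escape genes, because the difference between 28 escape genes and the rest (-0.012) had an interval from -0.085 to 0.158. An effect of the short XIST isoform on the X chromosome stays a hypothesis beside it.

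The fall of ATF4 targets was not due to GFP replicate 1 alone, since the median without that library was -0.45. It was also kept after the correction for GC content, length and level (-0.56, interval -0.62 to -0.35). A difference in culture state between the groups, such as medium depletion, was not tested and stays open beside an effect of the construct.

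The rise of histone genes was not due to sXIST replicate 3 alone, since the median without it was 0.58 with the list still called. More RNA without a poly(A) tail in the sXIST libraries could raise them. Other such RNAs had a camera p of 0.0661 and a median of 0.80 (interval 0.49 to 0.86), with sXIST replicate 1 going the opposite way at -0.84, so this stays open.

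The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Each split but the real one mixes both groups on each side, so a difference between the groups widens its spread and shrinks its shift. The values of those splits are therefore not a measure of chance alone. The real split gave 1650 calls by edgeR against at most 0 in the others (1 of 10 as large), which had 138 to 1233 genes at an unadjusted p under 0.05 against 4491, and an X shift of 0.087 against at most 0.037 (1 of 10). The odds ratio for falls on X, 2.05 in the real split, could not be computed in the others because they had 0 calls (1 of 10 by default), so it adds nothing to the comparison of calls. For the number of lists called, 13 in the real split, the highest of the others was also 13, and 3 of the 10 splits gave as many.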
